A study of Mus musculus with 594 samples.

How the data were processed

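The mouse lines αTC1 and βTC3 were seeded, per the labels' protocols, in low-glucose medium with serum 24 h before compounds in DMSO were added, and lysed after 1, 6 or 24 h. From 1 µg of total RNA biotin-labelled cRNA was made and hybridised to Affymetrix HT mouse arrays. The authors deposited 1 intensity per probe set and array, made with RMA per the submitters' processing notes. The RMA version and any further scaling or batch correction are not given. The deposited intensities, from 3.962 to 13635, are on a linear scale, although the design had assumed log2 values, so log2 was taken here before all tests.

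The table held 22716 probe sets on 594 arrays. Of these 18003 carried 1 gene symbol in the mouse annotation used, 287 carried several, and 4426 had no name there. The last 2 kinds, with 90 array controls among them, were left out. Each of the 11807 genes was represented by its probe set with the highest mean (4150 genes had more than 1). Among 208 comparisons of named genes with more than 1 probe set, 8 had probe sets of opposite sign beyond a log2 of 0.1. Array medians ran from 4.363 to 4.729 on the log2 scale (SD 0.0421), and the largest shift of a comparison's median change was 0.076 under centring and 0.061 under quantile normalization.

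Line, compound, dose, time, batch and array plate (9 plates) came from the sample titles, as did the replicate number of arrays with a compound, since DMSO titles hold none. Tests were made with limma 3.58.1 in R 4.3.3 (with the package data.table, version 1.17.8), with empirical Bayes variances. Each line and time was fitted alone with all its arrays and with the 7 batches, numbered 4 to 10, as a fixed term. Classes were averaged with equal weight per compound. Differences between the lines, and DMSO over time, used joint fits with the batch term. p-values were adjusted by Benjamini-Hochberg over genes within a comparison, genes with an adjusted p under 0.05 were called, and 2-fold needs a log2 change of at least 1. With 2 to 4 arrays per compound p-values rest only on spread within all groups fitted. This spread may be technical, as each line is a single culture.

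The 21 gene lists were cholesterol synthesis, fatty acid synthesis, beta cell markers, alpha cell markers, other islet hormone cells, non-endocrine cells, histone genes, mitosis, DNA replication, CDK inhibitors, targeted chromatin enzymes, neuronal genes, ER and amino acid stress, oxidative stress (NRF2), heat shock, p53 targets, immediate early genes, germline genes, imprinted genes, interferon response, and lysosome and autophagy. Members absent from the table were left out. Lists were tested with limma's camera, with its preset correlation between genes and also with an estimated one, adjusted over lists within a comparison.

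Samples, groups, comparisons, lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, for each comparison at 24 h and line, the 6 largest rises and 6 largest falls among called genes with the same sign in every array or compound, up to 4 called members of each list, and genes set beforehand, among them Gcg, Ins1, Ins2, Pdx1, Cdkn1a, H1f0, Hdac1, Ehmt2 and Dnmt1. "The same sign" was read, after a first output, as no overlap between groups in the comparisons of classes, pairs, lines and times. For length the text names a part of these genes, picked after the values were seen, and some whose call hung on 1 array were left out. Genes named at 1 h or 6 h, and the tests of zebuarine and scriptaid alone, were also chosen after the values were seen.

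In simulated data 66 to 68 genes changed at each size. For BIX-01294 the code recovered 70.6% at a log2 change of 0.5 and 100% at 1 (10 false calls). The values were 98.5% and 100% for hydroxamic acids (16 false calls), 48.5% and 95.5% for a pair of compounds (8), and 38.2% and 97% for a line difference (14). With nothing changed limma made 0 calls. Camera called only the list raised by 0.5, and r across lines was 0.93 for equal and -0.01 for unrelated profiles. In real arrays genes correlate, so errors may be more frequent.

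Alternatives were no batch term, array plate as a random block, another quantile normalization, arrays centred on their medians, genes below the median level left out, the mean of all probe sets per gene, only the arrays of the groups compared, only compounds in batches 4 to 6, a replicate block, one adjustment over all comparisons of a compound with DMSO, Spearman's rho, all genes in the correlations, and each replicate or compound left out in turn.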

Results

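Gene expression was measured in a pair of mouse pancreatic endocrine tumour lines, αTC1, which makes glucagon, and βTC3, which makes insulin. Cells were exposed to 1 of 29 small molecules that act on chromatin-modifying enzymes, or to the solvent DMSO, for 1, 6 or 24 h before RNA was hybridised to Affymetrix arrays. The compounds comprised 8 hydroxamic acids, 3 ortho-amino anilides and 2 cyclic tetrapeptides, all of which inhibit histone deacetylases. The others were the histone lysine methyltransferase inhibitors BIX-01294 and chaetocin, the arginine methyltransferase inhibitor AMI-1, 3 inhibitors of DNA methylation and 10 compounds given by code name only. There were 299 arrays of αTC1 and 295 of βTC3. A compound group held 3 arrays at each time, except for 5 groups of 2 and 1 group of 4, all in αTC1 at 24 h, and the DMSO groups held 10 to 14 arrays per line and time. Each compound was given at 1 dose, from 0.015 µM for LBH-589 to 10 µM. The number of arrays limits the precision of every value below. Many counts, several at 1 h, moved by over 1.5 times with another choice of arrays or batch term, as listed at the end. Values after a gene name are log2 changes ± SE unless another unit is given.

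The lines were first compared in DMSO, which gives the baseline of the compound effects and checks the labels. At 24 h αTC1 expressed the glucagon gene Gcg 10.9 times as high as βTC3 (3.44 ± 0.30, adjusted p = 8.5e-11), with log2 levels of 12.32 ± 0.25 (SD, n = 14) against 8.79 ± 1.49 (SD, n = 12). Insulin (Ins2) was lower in αTC1 by a log2 change of -8.88 ± 0.18, and the β cell transcription factor Pdx1 by -5.22 ± 0.13. 6 of the 8 alpha cell markers were higher and 1 was lower (6 and 1 adjusted over the list alone, median log2 2.81, camera adjusted p = 0.0137, adjusted p = 0.0711 with an estimated correlation), led by the transcription factors Irx1 (4.40 ± 0.063), Irx2 (3.74 ± 0.07) and Pou3f4 (3.59 ± 0.094). 1 of the 11 beta cell markers was higher and 7 were lower (1 and 7 adjusted over the list alone, median log2 -2.12, camera adjusted p = 3.7e-04, adjusted p = 0.0711 with an estimated correlation), among them Pcsk1, which cleaves proinsulin (-6.88 ± 0.096), and Sytl4, which docks insulin granules (-5.76 ± 0.081). Among genes higher in αTC1 the largest measured differences were in Cps1, the mitochondrial enzyme that makes carbamoyl phosphate for the urea cycle (8.24 ± 0.099), Sgk1 (7.55 ± 0.061) and Lpl, lipoprotein lipase (7.53 ± 0.08). Neuropeptide Y (Npy, -9.06 ± 0.086) and somatostatin (Sst, -8.69 ± 0.11) were higher in βTC3. The lower of the levels compared lay near background (Npy 3.89 and Ins2 4.31 in αTC1, Cps1 3.49 in βTC3), where arrays compress differences, so no fold is given here. Imprinted genes differed in both directions, with Igf2 at -7.02 ± 0.097 and Grb10 at 5.56 ± 0.085. 1 of the 15 ER and amino acid stress genes was higher and 11 were lower (1 and 12 adjusted over the list alone, camera adjusted p = 0.0019, adjusted p = 0.191 with an estimated correlation). With limma and an adjusted p under 0.05, 6948 genes differed at 1 h, 6920 at 6 h and 7038 at 24 h, of which 3623 were higher in αTC1 and 3415 higher in βTC3. Ins1 and H1f0 were not analysed here.

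Time in culture without compound also changed expression, read as DMSO at 24 h against 1 h. The immediate early transcription factor Egr1 fell in αTC1 (-2.74 ± 0.13, 6.68-fold, adjusted p = 8.62e-20, n = 14 and 14) and in βTC3 (-2.42 ± 0.14, 5.34-fold, n = 12 and 12). Fos fell with it (-2.52 ± 0.16 and -0.94 ± 0.11). Nr4a1, another rapidly induced transcription factor, fell in αTC1 (-1.35 ± 0.11). In βTC3 the sterol synthesis enzymes Msmo1 (1.18 ± 0.12) and Lss (1.13 ± 0.16) and the stearoyl-CoA desaturase Scd1 (1.02 ± 0.10) rose, and Gcg fell (-0.63 ± 0.14). In total 570 genes rose and 289 fell in αTC1, and 784 rose and 457 fell in βTC3, and without the batch term 360 genes changed in αTC1 and 598 in βTC3. Compounds were therefore compared only with DMSO of the same time.

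Each compound was next set against DMSO at its own time and line. At 1 h, 16 compounds in αTC1 and 17 in βTC3 changed at least 1 gene, and none changed over 80, the number for CRA-024781 in βTC3. At 6 h, 19 compounds in αTC1 and 20 in βTC3 changed over 1000 genes, up to 4709 for pyroxamide in αTC1 and 4926 for trichostatin A in βTC3. At 24 h the numbers over 1000 were 19 and 18 compounds, with the highest counts for chaetocin in αTC1 (5656) and PXD101 in βTC3 (5003). Responses fell back between 6 and 24 h for scriptaid, from 3701 to 50 genes in αTC1 and from 3584 to 6 in βTC3, and for BRD-K92415738, from 4040 to 63 and from 4348 to 121. Counts rose over the same interval for BRD6929, from 12 to 3005 genes in αTC1 and from 31 to 2779 in βTC3, and for BRD5298, from 267 to 3823 and from 77 to 3070. AMI-1 changed 0 genes at each time in each line by limma, with 229 genes at an unadjusted p under 0.05 in αTC1 and 490 in βTC3 at 24 h, where chance gives 590. RG-0108 changed 0 genes at 24 h in either line, with 745 and 651 genes at an unadjusted p under 0.05. Scriptaid at 6 h in αTC1 raised Rsad2, an interferon-induced antiviral protein (3.26 ± 0.19), and lowered the potassium channel gene Kcnk2 (-3.65 ± 0.17). At 24 h these genes, chosen after their values were seen, read 0.82 ± 0.45 and -0.15 ± 0.33. The split of the scriptaid calls at 6 h in αTC1, 2085 up and 1616 down, was 1756 and 2126 with arrays centred on their medians. The 50 calls at 24 h (23 up, 27 down) were 34 up and 25 down after another quantile normalization. Without replicate 1 scriptaid changed 2 genes in αTC1 at 24 h, and in βTC3 the counts without replicate 1, 2 and 3 were 1, 0 and 1.

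**Figure D1:**
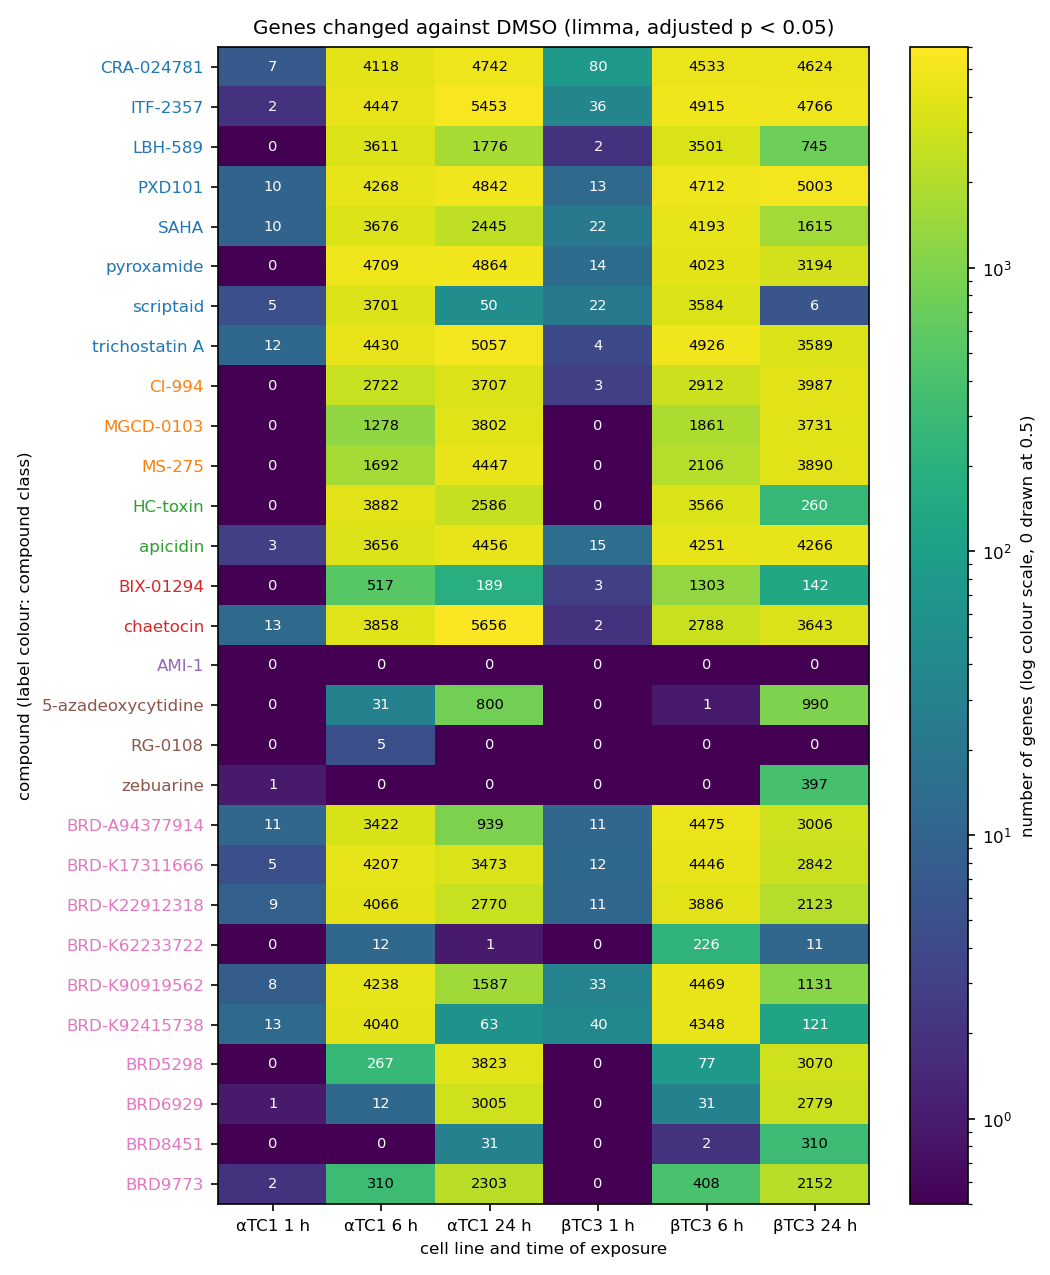
Number of genes changed against DMSO for each of the 29 compounds (vertical axis) in each line at each time (horizontal axis), from limma at an adjusted p under 0.05. Label colours mark hydroxamic acids (blue), ortho-amino anilides (orange), cyclic tetrapeptides (green), lysine methyltransferase inhibitors (red), AMI-1 (purple), DNA methylation inhibitors (brown) and code names (pink), and counts go from 0 to 80 at 1 h and up to 5656 at 24 h.

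The 8 hydroxamic acids as a class, each with equal weight, changed 5954 genes in αTC1 at 24 h. The glutathione transferase gene Gsta4 rose 28.1-fold (4.81 ± 0.15, adjusted p = 3.11e-38, 22 arrays against 14), Rsad2 25.1-fold (4.65 ± 0.20), the globin gene Hba-a1 by 3.86 ± 0.13 and Selenop, the plasma selenium carrier, by 3.50 ± 0.15. The crystallin gene Cryba2 fell (-3.22 ± 0.14, 9.31-fold), as did Kcnk2 (-2.91 ± 0.15) and the transaminase gene Bcat1 (-2.61 ± 0.13). 18 of the 18 mitosis genes fell (18 adjusted over the list alone, median log2 -0.92, camera adjusted p = 7.64e-13, adjusted p = 0.0512 with an estimated correlation), including Cdc20, an activator of the anaphase-promoting complex (-2.39 ± 0.11, 5.22-fold), and the kinase Plk1 (-1.67 ± 0.11). 12 of the 14 lysosome and autophagy genes rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.36e-06), led by the protease gene Ctsl (1.63 ± 0.068). 9 of the 12 immediate early genes rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 8.73e-04, adjusted p = 0.0512 with an estimated correlation), with Fos at 1.52 ± 0.14. 9 of the 10 interferon response genes rose (9 adjusted over the list alone, camera adjusted p = 0.00246, adjusted p = 0.0681 with an estimated correlation). 5 of the 8 alpha cell markers fell (5 adjusted over the list alone, camera adjusted p = 0.0298, adjusted p = 0.211 with an estimated correlation), among them Irx1 (-1.23 ± 0.086). Gcg stood at 0.08 ± 0.058 (adjusted p = 0.291) and at 0.14, past the threshold, without trichostatin A. The CDK inhibitor Cdkn1c rose (1.72 ± 0.11), and Cdkn1a by 0.34 ± 0.099. Histone genes split, with the linker histone H1f2 up (1.89 ± 0.11) and H2ax down (-1.44 ± 0.096), and this list was not called by camera (adjusted p = 0.902). In all 3084 genes rose and 2870 fell, 383 and 311 of them at least 2-fold.

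In βTC3 at 24 h the hydroxamic acids changed 5096 genes (2652 up, 2444 down). The glutathione transferase gene Gstk1 rose 7.34-fold (2.88 ± 0.11, adjusted p = 9.81e-35, 24 arrays against 12), the pyrimidine-degrading enzyme gene Dpyd by 2.71 ± 0.14 and the insulin family gene Insl6 by 2.46 ± 0.10. The decarboxylase gene Ddc fell (-1.82 ± 0.089), as did the adaptor subunit gene Ap4s1 (-2.17 ± 0.091) and Rbpms (-1.89 ± 0.086). 7 of the 11 beta cell markers fell (7 adjusted over the list alone, median log2 -0.82, camera adjusted p = 2.43e-05), among them Nkx2-2 (-1.75 ± 0.10, 3.36-fold), G6pc2, the islet glucose-6-phosphatase subunit (-1.60 ± 0.096), and Pdx1 (-1.06 ± 0.071, 2.09-fold). Ins2 was -0.01 ± 0.033 (adjusted p = 0.895). Its level lay near the top of the measured range, which can hide changes. 18 of the 18 mitosis genes fell (18 adjusted over the list alone, median log2 -0.94, camera adjusted p = 9.27e-23), with Cdc20 at -1.90 ± 0.078. 12 of the 15 ER and amino acid stress genes fell (12 adjusted over the list alone, camera adjusted p = 3.62e-05), led by Trib3 (-1.04 ± 0.12). The small heat shock protein gene Hspb1 rose (1.81 ± 0.097). Compounds differed within the class: ITF-2357, CRA-024781, PXD101, pyroxamide and trichostatin A each lowered 18 of 18 mitosis genes in both lines, while scriptaid lowered 0, LBH-589 0 in αTC1 and 1 in βTC3, and SAHA 6 and 7.

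**Figure D2:**
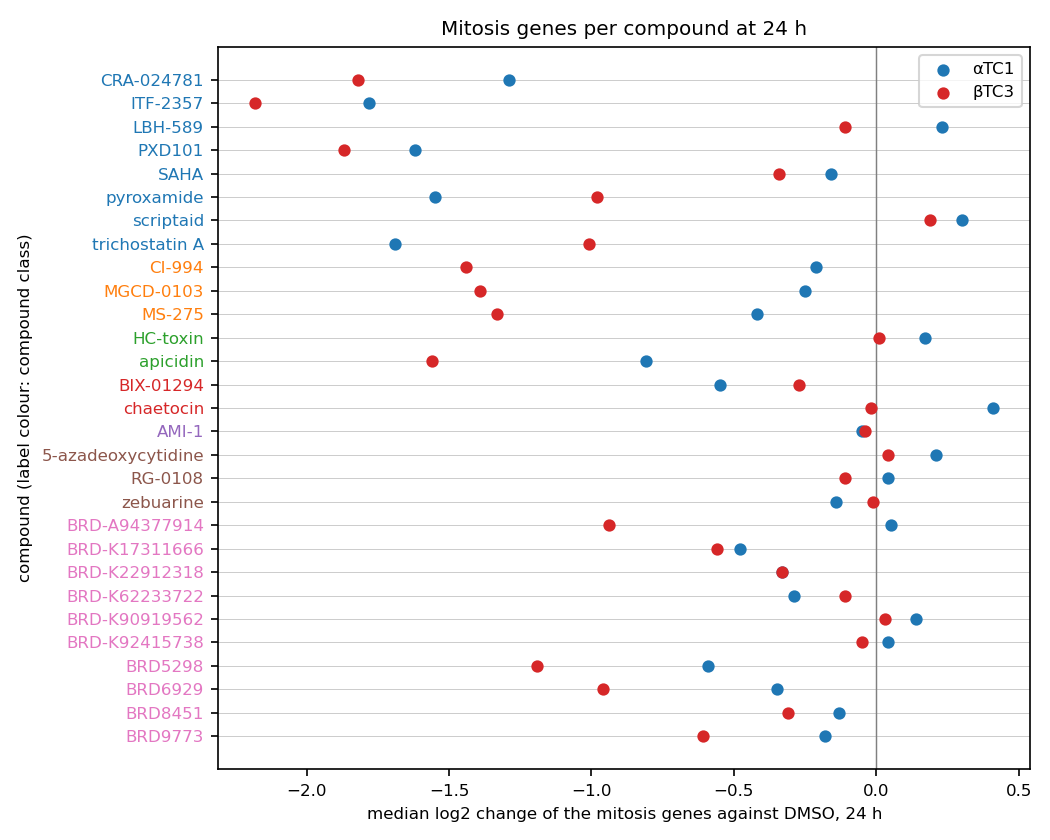
Median log2 change of the 18 measured mitosis genes at 24 h (horizontal axis) for each compound (vertical axis), in αTC1 (blue points) and βTC3 (red points). ITF-2357 stood lowest, at -1.78 and -2.18, and scriptaid lay above 0, at 0.30 and 0.19, with label colours marking the compound classes as in the plot of gene counts. The ITF-2357 arrays of βTC3 were all in batch 10.

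Earlier time points held part of this response, with genes named here chosen after their values were seen. At 1 h the hydroxamic acids changed 70 genes in αTC1 and 107 in βTC3. Txnip, which encodes a thioredoxin-binding protein induced by glucose, rose by 1.14 ± 0.12, 2.21-fold in αTC1 and 1.06 ± 0.073, 2.09-fold in βTC3. Sertad3 and the antiproliferative gene Tob2 rose in both lines (0.90 and 0.90 in αTC1, 0.79 and 1.03 in βTC3). 4 of the 12 immediate early genes rose (5 adjusted over the list alone, camera adjusted p = 1.31e-10) in βTC3, among them Ier3 (1.00 ± 0.089) and Junb (0.74 ± 0.093). At 6 h 6011 genes had changed in αTC1, with Rsad2 up (3.66 ± 0.10) and Kcnk2 down (-3.81 ± 0.088), and 5936 in βTC3, with Insl6 up (3.32 ± 0.088) and Nkx2-2 down (-2.77 ± 0.11, 6.81-fold). At that time 1 of the 18 mitosis genes rose and 17 fell (1 and 17 adjusted over the list alone, median log2 -0.81, camera adjusted p = 2.58e-10) in αTC1, and 17 of the 18 mitosis genes fell (17 adjusted over the list alone, median log2 -1.03, camera adjusted p = 2.37e-12) in βTC3. In the same samples 12 of the 17 cholesterol synthesis genes rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 3.9e-05) in αTC1. 13 of the 17 cholesterol synthesis genes rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 1.93e-05, adjusted p = 0.0813 with an estimated correlation) in βTC3. 6 of the 8 alpha cell markers fell (6 adjusted over the list alone, camera adjusted p = 3.25e-04) in αTC1. 7 of the 11 beta cell markers fell (7 adjusted over the list alone, camera adjusted p = 1.64e-04) in βTC3. The split at 6 h in αTC1, 3141 up and 2870 down, became 2804 and 3918 with centred arrays, and that at 1 h in βTC3, 83 and 24, became 67 and 45. Leaving out replicate 2 at 1 h left 27 calls in αTC1, and leaving out replicate 3 left 68 in βTC3.

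Under the 3 ortho-amino anilides at 24 h in αTC1 Selenop rose 49.5-fold (5.63 ± 0.21, adjusted p = 3.68e-34, 8 arrays against 14), and Rsad2 by 5.17 ± 0.28 and Gsta4 by 4.84 ± 0.21. Kcnk2 fell (-3.25 ± 0.20), and Gcg rose 1.43-fold (0.52 ± 0.081). 8 of the 10 interferon response genes rose (9 adjusted over the list alone, camera adjusted p = 8.2e-06), including Usp18, which removes ubiquitin-like ISG marks (1.58 ± 0.13). 8 of the 12 immediate early genes rose (8 adjusted over the list alone, camera adjusted p = 1.16e-04), with Fos at 2.67 ± 0.19. 13 of the 19 neuronal genes rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.00107). 7 of the 11 oxidative stress (NRF2) genes rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00512), led by the haem oxygenase gene Hmox1 (1.88 ± 0.19). Cdkn1c and Cdkn1a rose (2.73 ± 0.15 and 1.00 ± 0.14), as did Hdac1, which encodes a target of these inhibitors (0.88 ± 0.071). 1 of the 18 mitosis genes rose and 9 fell (1 and 9 adjusted over the list alone, median log2 -0.29, camera adjusted p = 0.02, adjusted p = 0.54 with an estimated correlation). The class changed 5169 genes in αTC1, 2507 up and 2662 down.

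In βTC3 at 24 h the anilides raised Rsad2 17-fold (4.09 ± 0.13, adjusted p = 4.04e-39, 9 arrays against 12), the calcium-binding protein genes Tesc (4.08 ± 0.18) and Calb1 (3.65 ± 0.15), and Gcg 2.32-fold (1.21 ± 0.14, adjusted p = 3.53e-12). The catecholamine synthesis gene Th fell (-2.30 ± 0.15), as did Nkx2-2 (-1.69 ± 0.13) and Pdx1 (-0.67 ± 0.092). Ins2, with the same limit, stood at 0.08 ± 0.043 (adjusted p = 0.128). 18 of the 18 mitosis genes fell (18 adjusted over the list alone, median log2 -1.37, camera adjusted p = 4.57e-22), with Cdc20 at -2.26 ± 0.10 and Plk1 at -2.02 ± 0.11. 7 of the 10 interferon response genes rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.00558). 6 of the 14 p53 targets rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.00558), among them Perp (1.87 ± 0.13). Hspb1 rose 9.13-fold (3.19 ± 0.13) and the CDK inhibitor Cdkn2b by 1.11 ± 0.092. The class changed 5162 genes, 2598 up and 2564 down.

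At 1 h the anilides changed 2 genes in αTC1, Ddit4, a stress-induced inhibitor of mTOR signalling (0.53 ± 0.10), and Ier3 (0.52 ± 0.10), and 3 in βTC3, Gadd45g (0.61 ± 0.10), Ddit4 (0.56 ± 0.095) and Cited2 (0.32 ± 0.067). The αTC1 count was 0 without CI-994, replicate 2 or replicate 3 and 1 without MGCD-0103 or MS-275, and the βTC3 count was 0 without CI-994 or replicate 3, with Cited2 also lost without MS-275 or replicate 1. With only the arrays compared limma called 0 genes in αTC1 (355 at an unadjusted p under 0.05) and 1 in βTC3. At 6 h 3141 and 3473 genes had changed. Rsad2 was up in αTC1 (3.90 ± 0.14) and in βTC3 (3.13 ± 0.13), values picked after they were seen like those at 1 h. 6 of the 10 interferon response genes rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 6.59e-04) in βTC3.

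The difference between both classes was tested in the same fit, although doses differed between compounds, so it compares these compounds at these doses. At 24 h in αTC1 the hydroxamic acids stood lower than the anilides in Hsd11b1, which regenerates active glucocorticoid (-2.56 ± 0.13, 5.89-fold), the glucuronosyltransferase gene Ugt1a6a (-2.48 ± 0.20), Selenop (-2.13 ± 0.20) and Gcg (-0.44 ± 0.077). They stood higher in Dcxr (1.55 ± 0.11). In βTC3 they stood lower in the matrix protein gene Ccn3 (-3.07 ± 0.17, 8.43-fold), Rsad2 (-1.94 ± 0.12), Tesc (-1.68 ± 0.17) and Gcg (-1.39 ± 0.12, 2.63-fold), and higher in the peptide gene Nmb (1.20 ± 0.12). Under hydroxamic acids, set against anilides, 16 of the 18 mitosis genes were lower (16 adjusted over the list alone, median log2 -0.68, camera adjusted p = 7.58e-13) in αTC1. 15 of the 18 mitosis genes were higher and 1 was lower (15 and 1 adjusted over the list alone, median log2 0.40, camera adjusted p = 2.5e-05, adjusted p = 0.089 with an estimated correlation) in βTC3. 9 of the 11 oxidative stress (NRF2) genes were lower (10 adjusted over the list alone, camera adjusted p = 8.06e-06) in αTC1. 8 of the 11 oxidative stress (NRF2) genes were lower (8 adjusted over the list alone, camera adjusted p = 6.95e-05) in βTC3. 11 of the 15 ER and amino acid stress genes were lower (13 adjusted over the list alone, camera adjusted p = 1.27e-07) in βTC3. 9 of the 14 targeted chromatin enzymes were lower (10 adjusted over the list alone, camera adjusted p = 2.66e-04) in αTC1. At 24 h 3261 genes differed in αTC1 and 3833 in βTC3, at 6 h 5286 and 5926, and at 1 h 49 and 93. With only the arrays compared the counts were 1106 and 2548 at 24 h, 3418 in αTC1 at 6 h, and 24 and 21 at 1 h, and with a replicate block added 1174 in αTC1 at 24 h. With only compounds of batches 4 to 6 the 1 h counts were 3 and 60. The 24 h split in βTC3, 1907 higher and 1926 lower under hydroxamic acids, became 2514 and 1637 with centred arrays. At 1 h, counts without replicates 2 and 3 fell to 8 and 31 in αTC1, and those without MGCD-0103 and MS-275 to 30 and 29. In βTC3 they were 40 without CI-994 and 47, 57 and 41 without replicates 1, 2 and 3.

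The cyclic tetrapeptides, apicidin at 1.4 µM and HC-toxin at 0.12 µM, changed 4250 genes in αTC1 and 3016 in βTC3 at 24 h. In αTC1 Rsad2 rose 23.9-fold (4.58 ± 0.29, adjusted p = 2.57e-21, 6 arrays against 14) and Gsta4 by 4.12 ± 0.22, and Kcnk2 fell (-2.46 ± 0.21). 10 of the 14 lysosome and autophagy genes rose (10 adjusted over the list alone, camera adjusted p = 2.1e-07). 8 of the 10 interferon response genes rose (8 adjusted over the list alone, camera adjusted p = 1.21e-05). 6 of the 10 histone genes fell (6 adjusted over the list alone, camera adjusted p = 0.00474), among them H2ax (-1.73 ± 0.14). In βTC3 Gstk1 rose (2.59 ± 0.16, adjusted p = 1.58e-21, 6 arrays against 12), as did Tesc (2.21 ± 0.21) and Insl6 (2.01 ± 0.14), and the fructose transporter gene Slc2a5 fell (-1.50 ± 0.11). 18 of the 18 mitosis genes fell (18 adjusted over the list alone, median log2 -0.76, camera adjusted p = 2.35e-21) in βTC3. 7 of the 11 beta cell markers fell (7 adjusted over the list alone, camera adjusted p = 3.99e-04) in the same line, led by Nkx2-2 (-1.42 ± 0.15). Taken alone, apicidin lowered 7 histone genes in αTC1 and 18 mitosis genes and 7 beta cell markers in βTC3, and HC-toxin 2, 0 and 1. At 1 h 7 genes changed in αTC1 and 3 in βTC3, and at 6 h 4619 and 4596. Without apicidin the 24 h counts were 2586 in αTC1 and 260 in βTC3. Without apicidin the βTC3 changes were -0.29 for Nkx2-2 and -0.13 for Slc2a5, no longer called, and 0.76 for Insl6 and 1.72 for Gstk1, and without HC-toxin -2.56 for Nkx2-2, -2.88 for Slc2a5 and 3.25 for Insl6. In αTC1 Kcnk2 read -1.10 without apicidin and -3.81 without HC-toxin. The 1 h counts without apicidin were 0 and 0 and without HC-toxin 3 and 15, and without replicates 1, 2 and 3 they were 0, 2 and 3 in αTC1 and 2, 6 and 1 in βTC3.

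BIX-01294, an inhibitor of the histone lysine methyltransferase encoded by Ehmt2, was given at 10 µM and raised genes of sterol synthesis at 24 h. In αTC1 13 of the 17 cholesterol synthesis genes rose (13 adjusted over the list alone, median log2 1.17, camera adjusted p = 4.35e-58). Among them were the sterol oxidase gene Msmo1 (1.54 ± 0.18, 2.91-fold, adjusted p = 5.43e-09, n = 3 against 14), lanosterol synthase Lss (1.40 ± 0.19), Mvd (1.37 ± 0.18) and Idi1 (1.34 ± 0.16). In βTC3 15 of the 17 cholesterol synthesis genes rose (15 adjusted over the list alone, median log2 0.97, camera adjusted p = 1.94e-62), with Lss (1.76 ± 0.24, 3.4-fold, adjusted p = 2.37e-07, n = 3 against 12) and Msmo1 (1.15 ± 0.15). From background knowledge, not from the labels, the study was taken before the analysis to have reported this list, so its direction here is not counted as independent evidence. 5 of the 10 fatty acid synthesis genes rose (8 adjusted over the list alone, camera adjusted p = 1.93e-14) in αTC1, led by Scd1 (1.26 ± 0.16). 3 of the 10 fatty acid synthesis genes rose (6 adjusted over the list alone, and 1 fell, camera adjusted p = 7.96e-09) in βTC3, led by the elongase gene Elovl6 (1.17 ± 0.18). In αTC1 4 of the 14 p53 targets rose (8 adjusted over the list alone, camera adjusted p = 4.79e-07), including Cdkn1a (1.04 ± 0.18, and 0.82, not called, without replicate 3). 7 of the 18 mitosis genes fell (14 adjusted over the list alone, camera adjusted p = 2.81e-17) in αTC1. Gcg fell in αTC1 (-0.38 ± 0.11, adjusted p = 0.0472), a call lost without any 1 of the 3 arrays (-0.38, -0.46 and -0.30). In βTC3 3 of the 15 ER and amino acid stress genes rose (7 adjusted over the list alone, camera adjusted p = 2.3e-07), with Trib3 at 1.32 ± 0.21, and the cationic amino acid transporter gene Slc7a3 rose (1.56 ± 0.19). The pancreatic transcription factor gene Mnx1 fell in βTC3 (-0.89 ± 0.19, and -0.76, not called, without replicate 1). 2 of the 18 mitosis genes fell (7 adjusted over the list alone, camera adjusted p = 7.96e-09) in βTC3. Ehmt2 itself read -0.34 ± 0.12, adjusted p = 0.188 in αTC1 and -0.33 ± 0.099, adjusted p = 0.0876 in βTC3. BIX-01294 changed 189 genes in αTC1 (85 up, 104 down) and 142 in βTC3 (102 up, 40 down). Without the batch term the counts were 77 and 39. With only the arrays compared the βTC3 count was 35, and without the arrays of plate 1 it was 324. Without replicate 1, 2 or 3 the counts were 116, 97 and 63 in αTC1 and 53, 60 and 51 in βTC3.

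**Figure D3:**
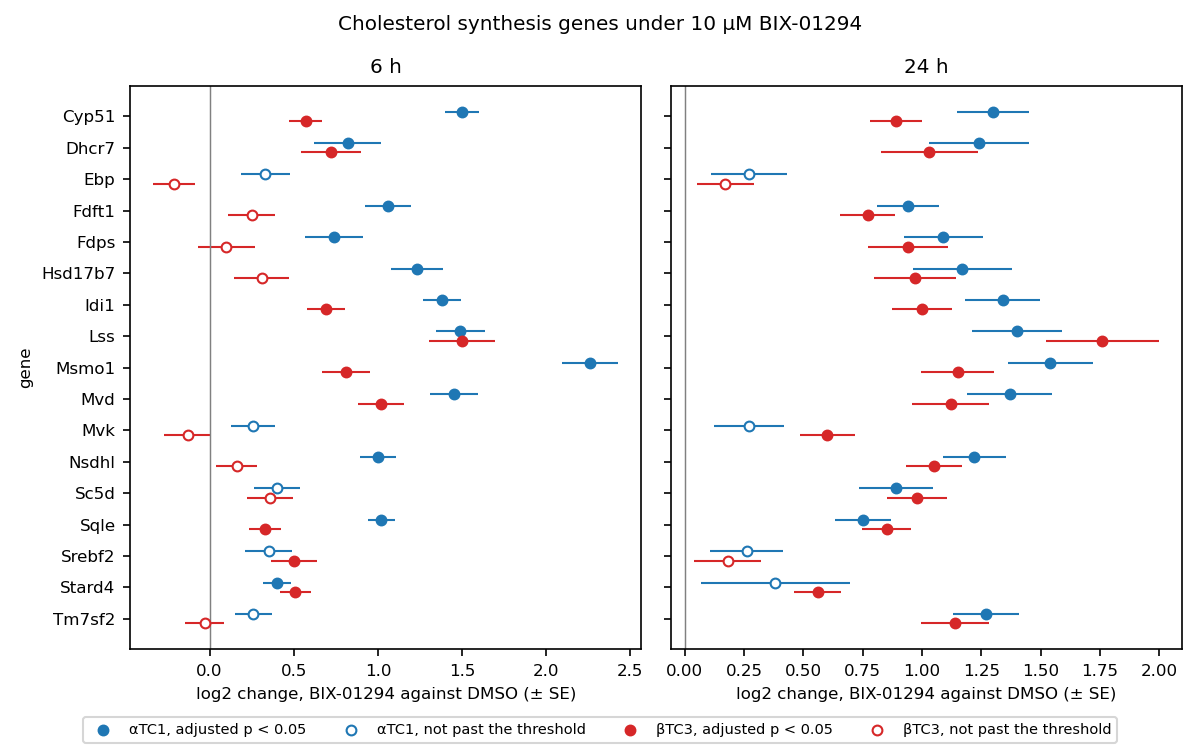
Log2 change ± SE of the 17 measured cholesterol synthesis genes (vertical axis) under 10 µM BIX-01294 against DMSO at 6 h and 24 h, in αTC1 (blue) and βTC3 (red), with filled points for genes at an adjusted p under 0.05. At 24 h 13 genes were past the threshold in αTC1 and 15 in βTC3, and at 6 h 12 and 9.

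At 6 h BIX-01294 changed 517 genes in αTC1 and 1303 in βTC3, with the genes named for 6 h and 1 h chosen after their values were seen. In αTC1 12 of the 17 cholesterol synthesis genes rose (16 adjusted over the list alone, camera adjusted p = 1.44e-52), again not independent evidence, with Msmo1 at 2.26 ± 0.17, 4.77-fold. In βTC3 14 of the 15 ER and amino acid stress genes rose (14 adjusted over the list alone, median log2 0.69, camera adjusted p = 2.81e-34). Trib3 rose 7.32-fold (2.87 ± 0.17), the transcription factor gene Ddit3 by 2.19 ± 0.18, Chac1, which degrades glutathione, by 1.95 ± 0.14 and Herpud1, a part of ER-associated degradation, by 1.50 ± 0.12. In αTC1 at the same time 1 of the 15 ER and amino acid stress genes rose and 5 fell (2 and 6 adjusted over the list alone, median log2 -0.12, camera adjusted p = 0.0278, adjusted p = 0.054 with an estimated correlation). Chac1 stood at -1.14 ± 0.13, Trib3 at -0.62 ± 0.14 and Ddit3 at 0.97 ± 0.20. 10 of the 18 mitosis genes fell (10 adjusted over the list alone, camera adjusted p = 9.12e-09) in βTC3 at 6 h. At 1 h in βTC3 3 of the 12 immediate early genes rose (6 adjusted over the list alone, camera adjusted p = 7.35e-24). The 3 genes called were Fos (1.12 ± 0.16), Nr4a1 (0.95 ± 0.12) and Egr2 (0.71 ± 0.12). With only the arrays compared limma called 0 genes (306 at an unadjusted p under 0.05), with near values and larger errors (1.06 ± 0.21, 0.96 ± 0.15 and 0.67 ± 0.14). In αTC1 0 genes passed limma's test at 1 h, with 467 at an unadjusted p under 0.05. Without replicate 3 the values for Ddit3 and Trib3 in αTC1 (0.65 and -0.59) and for Egr2 in βTC3 (0.40) were not called. Counts without single replicates were 255 (without 1) and 125 (without 3) in αTC1 at 6 h, 477 and 502 in βTC3, and 7 without replicate 2 in βTC3 at 1 h.

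Chaetocin, the other lysine methyltransferase inhibitor, was given at 1.7 µM and changed 5656 genes in αTC1 (2767 up, 2889 down) and 3643 in βTC3 (1817 up, 1826 down) at 24 h. In αTC1 the muscle enolase gene Eno3 rose 16.3-fold (4.02 ± 0.16, adjusted p = 3.92e-32, n = 4 against 14), H2-DMa, part of antigen loading on class II molecules, by 3.97 ± 0.19 and Cdkn1a by 2.43 ± 0.17. The surface protein gene Cd24a fell (-3.13 ± 0.15). In βTC3 P2rx7, an ATP-gated ion channel gene, rose 21.3-fold (4.41 ± 0.12, adjusted p = 1.5e-42, n = 3 against 12), Id1 by 3.13 ± 0.23 and Myc by 3.04 ± 0.17. Lactate dehydrogenase Ldha fell (-2.53 ± 0.49), as did Mnx1 (-2.05 ± 0.20) and Pdx1 (-0.96 ± 0.13). 11 of the 12 immediate early genes rose (11 adjusted over the list alone, median log2 1.05, camera adjusted p = 7.61e-06) in αTC1, with Fos at 3.71 ± 0.24. 10 of the 12 immediate early genes rose (11 adjusted over the list alone, median log2 1.55, camera adjusted p = 4.75e-15) in βTC3. 14 of the 19 DNA replication genes rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 1.46e-08) in βTC3. 14 of the 19 DNA replication genes rose and 1 fell (14 and 1 adjusted over the list alone, camera adjusted p = 7.45e-04, adjusted p = 0.107 with an estimated correlation) in αTC1, where Cdc6 rose by 2.26 ± 0.13. 10 of the 14 p53 targets rose (10 adjusted over the list alone, camera adjusted p = 1.02e-07) in βTC3. 8 of the 11 oxidative stress (NRF2) genes rose (8 adjusted over the list alone, camera adjusted p = 5.13e-06) in βTC3, with Hmox1 at 2.05 ± 0.17. 8 of the 10 interferon response genes rose (8 adjusted over the list alone, camera adjusted p = 1.02e-07) in βTC3, led by the chemokine gene Cxcl10 (2.69 ± 0.16).

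At 6 h chaetocin changed 3858 genes in αTC1 and 2788 in βTC3. 7 of the 10 heat shock genes rose (8 adjusted over the list alone, camera adjusted p = 4.88e-06) in αTC1, led by Hspa1b (4.08 ± 0.18), a value chosen after it was seen. At 1 h it lowered 12 of 13 called genes in αTC1, among them the phosphatase gene Dusp1 (-1.33 ± 0.14). 3 of the 12 immediate early genes fell (6 adjusted over the list alone, camera adjusted p = 1.26e-16). In βTC3 at 1 h the 2 calls were Zcchc3 (-0.91 ± 0.11) and Tiparp (-0.63 ± 0.083). The 1 h counts without replicates 1 and 2 were 4 and 6 in αTC1, the βTC3 count without replicate 1 was 6, and 1855 genes changed at 6 h in βTC3 without replicate 1.

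5-Azadeoxycytidine, a nucleoside that traps DNA methyltransferases, was given at 10 µM to both lines. It changed 0 genes at 1 h by limma (685 and 688 at an unadjusted p under 0.05 in αTC1 and βTC3), 31 and 1 at 6 h, and 800 and 990 at 24 h. In αTC1 at 24 h the germ cell gene Tex19.1 rose 6.17-fold (2.63 ± 0.23, adjusted p = 7.52e-14, n = 3 against 14), Fos by 2.38 ± 0.26, the tumour suppressor gene Rassf1 by 1.78 ± 0.12 and Txnip by 1.76 ± 0.25. Tenm4 fell (-1.23 ± 0.25). 2 of the 14 germline genes rose (2 adjusted over the list alone, median log2 0.04, camera adjusted p = 0.00372), the testis tubulin gene Tuba3a (1.56 ± 0.17) and Tex101 (1.45 ± 0.12). 6 of the 12 immediate early genes rose (7 adjusted over the list alone, camera adjusted p = 1.35e-09). 4 of the 19 DNA replication genes rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 4.11e-06). In βTC3 Id1 rose 4.91-fold (2.30 ± 0.24, adjusted p = 2.31e-11, n = 3 against 12), with Gadd45b (1.76 ± 0.14), Myc (1.63 ± 0.17) and Tuba3a (1.07 ± 0.13). 8 of the 12 immediate early genes rose (8 adjusted over the list alone, camera adjusted p = 3.76e-22) in βTC3. Imprinted genes also passed camera in αTC1 (1 of 10 up, 3 adjusted over the list alone, median log2 0.17, camera adjusted p = 0.0373). Dnmt1, the maintenance methyltransferase gene, read -0.11 ± 0.12, adjusted p = 0.742 in αTC1 and 0.11 ± 0.12, adjusted p = 0.69 in βTC3. The calls at 24 h split into 304 up and 496 down in αTC1, and this split turned with the scaling, to 349 and 409 with centred arrays and 379 and 319 after another quantile normalization. In βTC3 it was 394 and 596, and 456 and 424 after quantile normalization, and at 6 h in αTC1 18 and 13, and 20 and 7. Without replicate 1, 2 or 3 the 24 h count in αTC1 was 492, 400 and 357. In βTC3 it was 567 without replicate 1 and 376 without replicate 3. At 1 h in αTC1 1 gene was called without replicate 2, and at 6 h the counts were 0, 6 and 91 in αTC1 and 0 in βTC3.

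Zebuarine at 10 µM, another inhibitor of DNA methylation, was tested at 24 h after the other results had been seen. In βTC3 it changed 397 genes (182 up, 215 down). With only the arrays compared the count was 121. As many genes were given by 5 of 100 random splits of those arrays (3 of 100 in a second draw), so this count alone cannot exclude chance. Rises were those of Fos (1.50 ± 0.15, 2.82-fold, adjusted p = 6.17e-12, n = 3 against 12), Gadd45b (1.40 ± 0.14), Ier3 (1.37 ± 0.13) and Id1 (1.36 ± 0.24). Lss fell (-0.94 ± 0.25, not called without replicate 1 or 2, at -0.85 and -0.91). 7 of the 12 immediate early genes rose (9 adjusted over the list alone, median log2 0.72, camera adjusted p = 2.44e-22). 5 of the 17 cholesterol synthesis genes fell (10 adjusted over the list alone, camera adjusted p = 3.84e-08). In αTC1 0 genes passed limma's test, with 898 at an unadjusted p under 0.05, and Fos read 0.12 ± 0.26. Without replicate 1 or 2 the βTC3 count was 129 or 191.

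**Figure D4:**
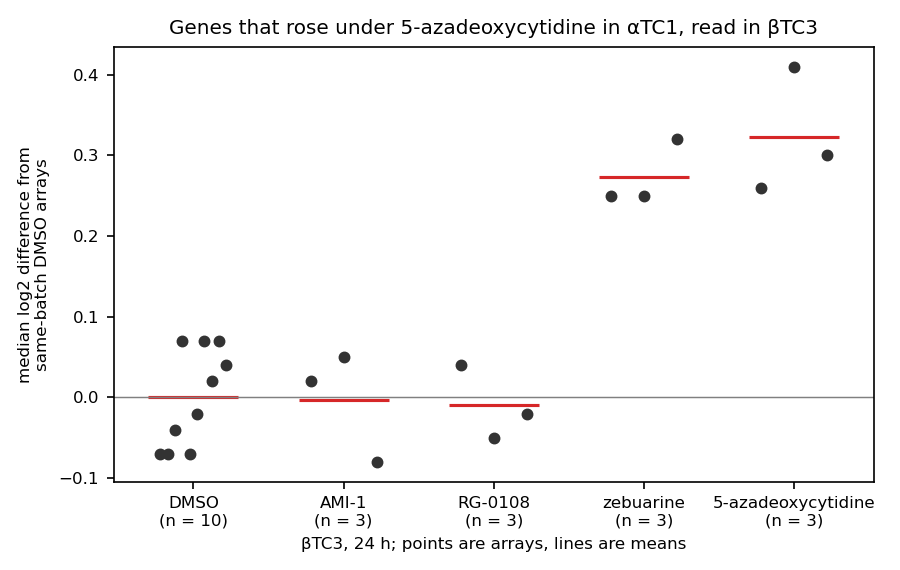
Median log2 difference from same-batch DMSO arrays (vertical axis) in each βTC3 array at 24 h (points, with red lines at the means), over the 304 genes that rose under 5-azadeoxycytidine in αTC1, for DMSO and 4 compounds (horizontal axis). Zebuarine arrays lay at 0.25 to 0.32 and 5-azadeoxycytidine arrays at 0.26 to 0.41, against -0.05 to 0.04 for RG-0108 and -0.08 to 0.05 for AMI-1.

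Compounds given at the same dose, 10 µM, were compared directly at 24 h. ITF-2357 and pyroxamide are both hydroxamic acids. In αTC1 ITF-2357 stood above pyroxamide in Tex19.1 (3.60 ± 0.29, 12.2-fold, adjusted p = 5.39e-15, n = 3 each) and the pituitary hormone subunit gene Cga (1.92 ± 0.27), and below it in Ddc (-1.85 ± 0.27). In βTC3 it stood above pyroxamide in the actin-bundling protein gene Fscn1 (3.65 ± 0.39, 12.6-fold) and below it in Hepacam2 (-3.80 ± 0.25), G6pc2 (-3.52 ± 0.23, 11.5-fold) and Pdx1 (-2.07 ± 0.17, 4.21-fold). 17 of the 18 mitosis genes were lower (17 adjusted over the list alone, camera adjusted p = 8.34e-30) in βTC3 under ITF-2357. 7 of the 11 beta cell markers were lower (7 adjusted over the list alone, camera adjusted p = 3.39e-09) in the same cells. Gcg did not pass the test in αTC1 (-0.20 ± 0.14, 95% interval -0.48 to 0.08). The pair differed in 276 genes in αTC1 and 1927 in βTC3. Fitted with only its 6 arrays in αTC1, which leave 1 residual degree of freedom, limma called 0 genes (538 at an unadjusted p under 0.05), with Tex19.1 at 3.34 ± 0.45, Cga at 1.53 ± 0.28 and Ddc at -1.62 ± 0.43, so these calls rest on the variances of the other arrays. In αTC1 the count was 74, 101 and 562 without ITF-2357 replicates 1, 2 and 3 and 180 and 77 without pyroxamide replicates 1 and 2, and in βTC3 1264 without pyroxamide replicate 2.

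CI-994, an ortho-amino anilide, differed from ITF-2357 in 2526 genes in αTC1 and 2455 in βTC3, and from pyroxamide in 1789 and 1511. In αTC1 it stood above ITF-2357 in Hsd11b1 (3.88 ± 0.28, 14.7-fold, adjusted p = 1.24e-17, n = 2 against 3) and below it in the alcohol dehydrogenase gene Adh4 (-3.78 ± 0.40) and Nr4a2 (-3.26 ± 0.37). Under CI-994 17 of the 18 mitosis genes were higher (17 adjusted over the list alone, camera adjusted p = 9.96e-25). 7 of the 8 alpha cell markers were higher (7 adjusted over the list alone, camera adjusted p = 3.33e-07). In βTC3 CI-994 stood above ITF-2357 in Hepacam2 (3.83 ± 0.28, 14.2-fold), G6pc2 (3.58 ± 0.25), Pdx1 (1.92 ± 0.19) and Gcg (1.69 ± 0.28). 5 of the 11 beta cell markers were higher (6 adjusted over the list alone, camera adjusted p = 1.5e-06) under CI-994 there. Against pyroxamide it stood higher in Ugt1a6a in αTC1 (3.40 ± 0.42, 10.6-fold) and in Ccn3 (3.89 ± 0.37, 14.9-fold), the cyclin gene Ccnd2 (3.09 ± 0.34) and Gcg (1.79 ± 0.26) in βTC3. 17 of the 18 mitosis genes were higher (17 adjusted over the list alone, camera adjusted p = 8.57e-23) in αTC1. The split of the CI-994 and ITF-2357 difference in βTC3, 1246 higher and 1209 lower under CI-994, became 1030 and 1669 with centred arrays. In αTC1 the counts without CI-994 replicates 1 and 2 were 1629 and 1677 against ITF-2357 and 996 and 1063 against pyroxamide.

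5-Azadeoxycytidine and zebuarine differed in 731 genes in αTC1 and 27 in βTC3. The αTC1 count was 59 without the arrays of plate 1, 286 without the batch term and, with only the arrays of the pair, 1077 and, with a replicate block added, 2129. In αTC1 Tex19.1 stood higher under 5-azadeoxycytidine (2.73 ± 0.28, 6.62-fold, adjusted p = 9.68e-11, n = 3 each), as did Fos (2.26 ± 0.32) and Tuba3a (1.83 ± 0.21). 2 of the 14 germline genes were higher (2 adjusted over the list alone, camera adjusted p = 4.21e-04) there. 8 of the 19 DNA replication genes were higher (10 adjusted over the list alone, camera adjusted p = 2.8e-07). In βTC3 Fos did not pass the test (0.20 ± 0.17, 95% interval -0.15 to 0.55). The calcium-binding protein gene S100a6 (0.85 ± 0.14) and Tuba3a (0.84 ± 0.15) stood higher, although neither was called without 5-azadeoxycytidine replicate 3 (0.54 and 0.75) or with only the arrays of the pair (0.85 and 0.84), a fit that called 1 gene. The αTC1 split, 276 higher and 455 lower, became 318 and 299 after another quantile normalization. The αTC1 count was 285, 426 and 411 without 5-azadeoxycytidine replicates 1, 2 and 3 and 229 and 330 without zebuarine replicates 2 and 3. The βTC3 count was 1, 4 and 11 without 5-azadeoxycytidine replicate 3 and zebuarine replicates 1 and 3.

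Whether an effect depended on the line was tested as the difference of the 24 h changes, βTC3 minus αTC1. Under hydroxamic acids the difference was 3.19 ± 0.16 for Tesc, which fell in αTC1 and rose in βTC3, and -3.46 ± 0.17 for Gsta4, which rose more in αTC1. Under anilides it was 4.24 ± 0.21 for Tesc, 3.12 ± 0.17 for Hspb1 and 0.70 ± 0.16 for Gcg. Also under anilides, 17 of the 18 mitosis genes had a lower change (18 adjusted over the list alone, camera adjusted p = 8.59e-15) in βTC3. Under cyclic tetrapeptides Gsta4 (-3.77 ± 0.25) led, and 7 of the 10 interferon response genes had a lower change (7 adjusted over the list alone, camera adjusted p = 3.27e-06) in βTC3. Pdx1 differed under hydroxamic acids (-0.79 ± 0.13). Under BIX-01294 the difference was 1.50 ± 0.26 for Slc7a3 and -1.09 ± 0.21 for Cdkn1a (-0.87, not called, without αTC1 replicate 3), and 0 of the 17 cholesterol synthesis genes differed (camera adjusted p = 0.162). At 6 h, tested after the data were seen, 7 of the 17 were lower in βTC3 (9 adjusted over the list alone, median -0.54, camera adjusted p = 3.62e-10). Chaetocin acted apart on Fbp1, a gluconeogenic enzyme gene (3.12 ± 0.26), and the transcription factor gene Nfix (-3.39 ± 0.25). 5-Azadeoxycytidine did so on Nupr1 (2.07 ± 0.39) and Tex101 (-1.31 ± 0.15), and zebuarine on Ier3 (1.56 ± 0.22). Under zebuarine 4 of the 12 immediate early genes had a higher change (6 adjusted over the list alone, camera adjusted p = 1.26e-08) in βTC3. The difference passed the test for 4231 genes under hydroxamic acids, 3289 under anilides, 2836 under cyclic tetrapeptides, 26 under BIX-01294, 3396 under chaetocin, 79 under 5-azadeoxycytidine and 140 under zebuarine. The chaetocin split, 1899 up and 1497 down, became 1633 and 2076 with centred arrays. Single arrays moved the smaller counts: for BIX-01294 they fell to 16 and 8 without αTC1 replicates 1 and 2 and to 14, 16 and 12 without βTC3 replicates 1, 2 and 3. For 5-azadeoxycytidine they were 50, 44 and 43 without αTC1 replicates 1, 2 and 3 and 49 and 32 without βTC3 replicates 1 and 3. For zebuarine they were 212, 29 and 38 without αTC1 replicates 1, 2 and 3 and 24 and 49 without βTC3 replicates 1 and 2, and for the cyclic tetrapeptides 1137 without apicidin and 1596 without replicate 1.

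Compound profiles were compared by Pearson's r across genes, between log2 changes of compounds in αTC1 and in βTC3. The lines share no DMSO array. Genes are not independent replicates, so the labels of the 29 compounds were permuted, two-sided, with 100000 resamples. Genes called for at least 1 compound were used. At 24 h, over 10270 genes, the same compound gave a mean r of 0.45 and different compounds 0.24 (p = 1e-05, the smallest these resamples can give). The values were 0.46 and 0.24 at 6 h over 9828 genes and 0.35 and 0.20 at 1 h over 185 genes, each with the same p. Class alone could give this p, so it does not show compound-specific profiles. Over all 11807 genes the 1 h means were 0.08 and 0.04, which did not differ (p = 0.2). The best match of an αTC1 profile was its own compound for 3 of 29 compounds at 1 h, 8 at 6 h and 11 at 24 h, among the 11 BIX-01294 (r = 0.38), chaetocin (0.59) and 5-azadeoxycytidine (0.53). RG-0108 and zebuarine gave r of -0.08 and -0.20 with themselves at 24 h. Within the hydroxamic acids and anilides, mean r between members of the same class exceeded that between classes at 1 h (0.51 against 0.03, and 0.12 against 0.01 over all genes) and 6 h (0.67 against 0.17). The p of 0.00606 was the smallest that a two-sided exact test over all assignments of the classes can give, and at 24 h mean r was 0.41 against 0.44 (p = 0.879). Adjusted by Benjamini-Hochberg over these 6 tests, p was 2e-05 for each test of compounds. For the classes it was 0.00727 at 1 h and 6 h and 0.879 at 24 h.

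**Figure D5:**
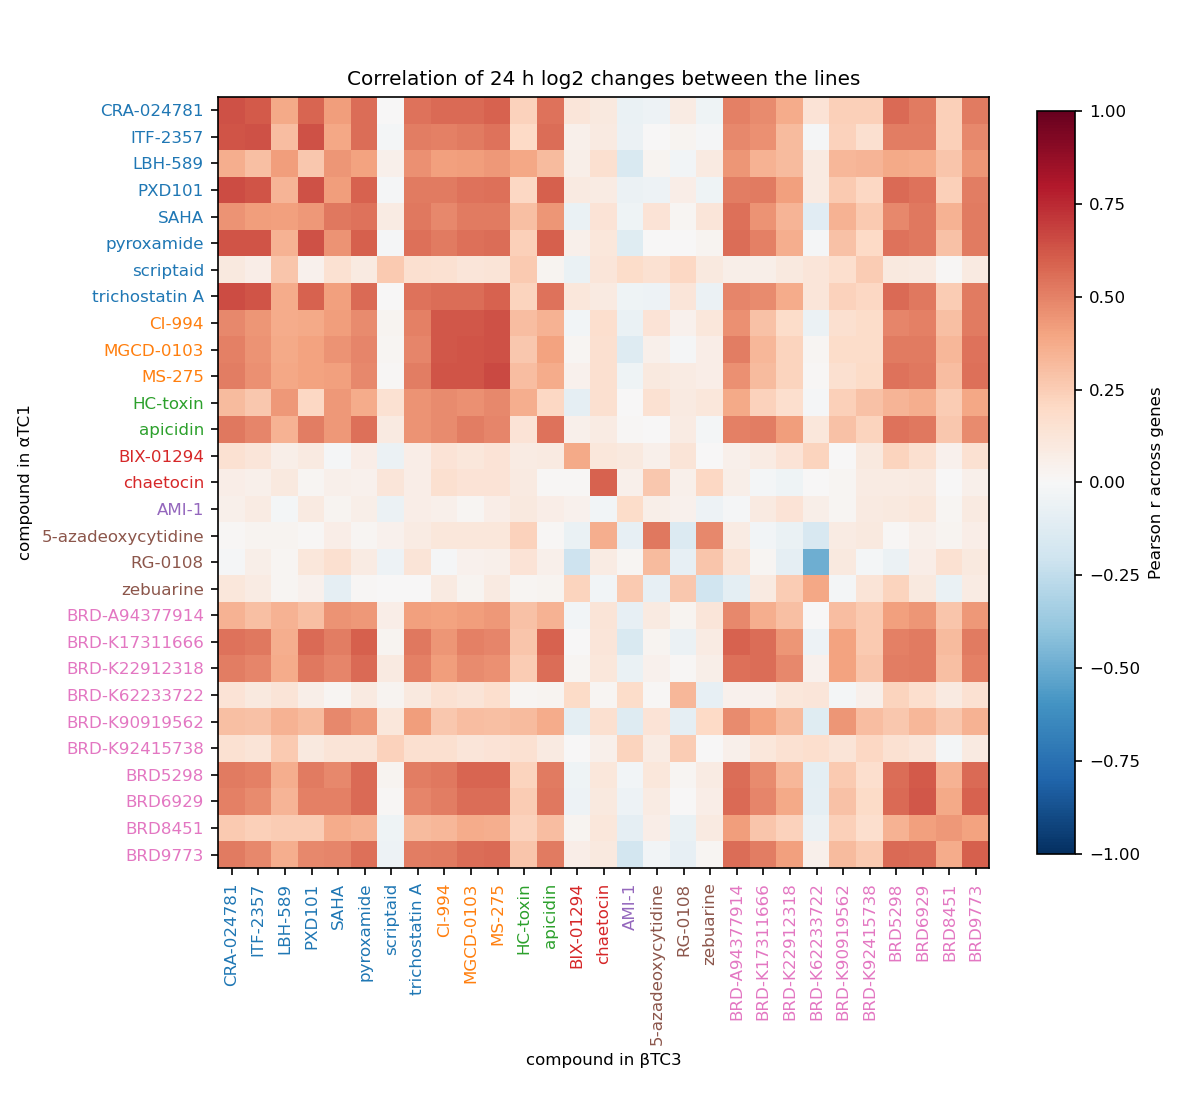
Pearson r across 10270 genes between the 24 h log2 changes of each compound in αTC1 (vertical axis) and in βTC3 (horizontal axis), with label colours marking the compound classes as in the plot of gene counts. Hydroxamic acids other than scriptaid, anilides and apicidin share values from 0.27 upwards, and chaetocin and BIX-01294 stand out on the diagonal at 0.59 and 0.38.

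Of 332 list calls made by camera with its preset correlation, 184 held with an estimated correlation, and for none of the 332 did the list's median, mean and test differ in sign. Of the 21 lists, those of non-endocrine cells and other islet hormone cells were called in no comparison. The lowest camera adjusted p was 0.0806 for the 13 non-endocrine cell genes, under chaetocin in αTC1 at 24 h, and 0.109 for the 7 other islet hormone cell genes, under hydroxamic acids in βTC3 at 1 h. Single members still passed the gene test, with 6 non-endocrine cell genes up and 1 down under chaetocin (median log2 0.17, 6 and 1 adjusted over the list alone).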

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

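The tests in this part were chosen after the results were seen, except those of array plate 1 and of the doses, whose outcomes were predicted before their values were examined.

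Effects differed between the lines by a test of the difference itself at 24 h for 4231 genes under hydroxamic acids, 3289 under ortho-amino anilides, 2836 under cyclic tetrapeptides, 26 under BIX-01294, 3396 under chaetocin, 79 under 5-azadeoxycytidine and 140 under zebuarine. 1 array stood far from the others of its group, with a gap of 0.9 of the group's range, for the level of Cdkn1a in αTC1 after 24 h of chaetocin (n = 4). Of 13 sets of values tested for such an array 1 was picked out, and chance picks out about 1 in 20, or 0.7 here.

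Zebuarine changed 397 genes in βTC3 and 0 in αTC1 at 24 h by limma, with 898 αTC1 genes at an unadjusted p under 0.05. Array plate 1, picked after array quality was seen, did not hide responses: for 6 compounds with αTC1 arrays both on it and elsewhere, the response on plate 1 was 1.11 times that on other plates (median, 0.96 to 1.47). Whether the βTC3 zebuarine arrays may hold 5-azadeoxycytidine samples cannot be told apart from a real effect, since 27 genes differed between both compounds there and 3 arrays against 3 allow too few splits to test that count. Without plate 1 the line difference fell from 140 genes to 8, with 2 of the 3 αTC1 zebuarine arrays lost. A cell type difference stays open and untested.

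Mitosis genes fell at 24 h under ITF-2357, CRA-024781, PXD101, pyroxamide and trichostatin A, whereas in αTC1 and βTC3 scriptaid lowered 0 and 0, LBH-589 0 and 1, and SAHA 6 and 7 of the 18. A loss of response in batches 5 and 6, which hold most arrays of the weaker compounds, is argued against by trichostatin A in those batches (mean of the array medians -1.33, from -1.81 to -0.71 in 4 arrays). Untreated samples under the labels of LBH-589 and SAHA are argued against as well, because 11 of their 11 arrays lay above the highest DMSO array over genes that rose under the other 5 hydroxamic acids. For scriptaid only 1 of 5 arrays did so, which leaves open a response that had ended by 24 h, a lost compound or a wrong label. Doses cannot be told apart from compounds, as each was given at 1 dose, and a difference between the molecules is likewise open.

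ER and amino acid stress genes rose under BIX-01294 at 6 h in βTC3, and the test of the line difference, added after the data were seen, called 600 genes (343 up, 257 down) and 13 of the 15 list members as higher in βTC3 (14 adjusted over the list alone, median difference 0.79, camera adjusted p = 4.24e-33). Unequal batches are argued against weakly, by differences of 0.98 and 0.65 in the 2 batches with both lines (1 array per line, mean 0.81). Untreated αTC1 samples are argued against by their cholesterol synthesis medians, of which the lowest was 0.87 where DMSO arrays reached 0.08. A list already high in αTC1 is argued against by its level in DMSO, lower there by a median log2 of -0.69 (members from -3.39 to 0.71). A cell type difference is a hypothesis, found and tested on the same arrays.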

How the results depend on the processing

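All settings were fixed before the data were examined except the one without the arrays of plate 1, all settings for zebuarine and scriptaid, and the test of lists for BRD-K62233722, which were chosen after the results were seen. Of the recomputed counts and values of the comparisons 762 stayed within 1.5 times the count or on the same side of the threshold, 177 moved and 1 was weaker. Of the recomputed values of named genes 2984 kept direction and side of the threshold, 74 lost the call, 2 gained it and 0 changed sign. Of 332 list calls 184 held with an estimated correlation, 276 without the batch term and 314 with the mean of all probe sets. Centring the arrays moved no count of a main comparison by over 1.5 times, and Spearman's rho kept the 6 similarity tests on their side. Of the counts of single compounds 93 moved with one adjustment over all of them and 53 without the batch term. Over all genes the difference in r between the same and different compounds at 1 h fell from 0.14 to 0.03 (p = 0.2). The cause of these moves was not tested. Arrays with medians of 4.363 to 4.729 on the log2 scale limit what can be read in genes near background.

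Without the batch term the count went, from first to second value, for 5-azadeoxycytidine in αTC1 6 h (31 to 2), βTC3 6 h (1 to 0) and βTC3 24 h (990 to 609) and 5-azadeoxycytidine minus zebuarine in αTC1 24 h (731 to 286) and βTC3 24 h (27 to 7). It moved likewise for BIX-01294 in αTC1 6 h (517 to 308), αTC1 24 h (189 to 77), βTC3 6 h (1303 to 690) and βTC3 24 h (142 to 39) and DMSO over time in αTC1 (859 to 360) and βTC3 (1241 to 598). Further moves were for ITF-2357 minus pyroxamide in αTC1 24 h (276 to 161) and βTC3 24 h (1927 to 1214) and chaetocin in αTC1 1 h (13 to 6) and βTC3 1 h (2 to 1). Others were for cyclic tetrapeptides in αTC1 1 h (7 to 2) and βTC3 1 h (3 to 0) and hydroxamic acids in αTC1 1 h (70 to 35) and βTC3 1 h (107 to 55). More followed for anilides in αTC1 1 h (2 to 1) and βTC3 1 h (3 to 1) and scriptaid in αTC1 24 h (50 to 24) and βTC3 24 h (6 to 1). Counts also moved for the line difference under 5-azadeoxycytidine (79 to 44), BIX-01294 (26 to 7) and zebuarine (140 to 59). With only the arrays of the groups compared, counts moved for 5-azadeoxycytidine in αTC1 6 h (31 to 0) and βTC3 24 h (990 to 393) and 5-azadeoxycytidine minus zebuarine in βTC3 24 h (27 to 1). It moved likewise for BIX-01294 in αTC1 6 h (517 to 284), βTC3 1 h (3 to 0) and βTC3 24 h (142 to 35) and ITF-2357 minus pyroxamide in αTC1 24 h (276 to 0). Further moves were for chaetocin in βTC3 1 h (2 to 1) and cyclic tetrapeptides in αTC1 1 h (7 to 4) and βTC3 1 h (3 to 0). Others were for hydroxamic acids minus anilides in αTC1 1 h (49 to 24), αTC1 6 h (5286 to 3418), αTC1 24 h (3261 to 1106), βTC3 1 h (93 to 21) and βTC3 24 h (3833 to 2548) and anilides in αTC1 1 h (2 to 0) and βTC3 1 h (3 to 1). More followed for scriptaid in βTC3 24 h (6 to 1) and zebuarine in βTC3 24 h (397 to 121). Counts also moved for the line difference under BIX-01294 (26 to 14). With array plate as a random block they moved for 5-azadeoxycytidine in αTC1 1 h (0 to 1) and 5-azadeoxycytidine minus zebuarine in αTC1 24 h (731 to 353) and βTC3 24 h (27 to 45). It moved likewise for BIX-01294 in αTC1 1 h (0 to 1) and chaetocin in αTC1 1 h (13 to 22). Further moves were for cyclic tetrapeptides in αTC1 1 h (7 to 11) and βTC3 1 h (3 to 6) and hydroxamic acids in αTC1 1 h (70 to 131) and βTC3 1 h (107 to 198). Others were for scriptaid in αTC1 24 h (50 to 109) and the line difference under BIX-01294 (26 to 46) and zebuarine (140 to 66). Without the arrays of plate 1, a choice made after seeing the data, they moved for 5-azadeoxycytidine in βTC3 6 h (1 to 0) and 5-azadeoxycytidine minus zebuarine in αTC1 24 h (731 to 59). It moved likewise for BIX-01294 in βTC3 6 h (1303 to 710) and βTC3 24 h (142 to 324) and cyclic tetrapeptides in αTC1 1 h (7 to 11) and βTC3 1 h (3 to 1). Further moves were for hydroxamic acids in βTC3 1 h (107 to 171) and scriptaid in αTC1 24 h (50 to 108). Others were for the line difference under zebuarine (140 to 8). Without the genes below the median level they moved for 5-azadeoxycytidine in αTC1 6 h (31 to 49) and anilides in βTC3 1 h (3 to 5). It moved likewise for the line difference under 5-azadeoxycytidine (79 to 51). After another quantile normalization the count moved for 5-azadeoxycytidine in αTC1 1 h (0 to 2). With the mean of all probe sets per gene it moved for cyclic tetrapeptides in βTC3 1 h (3 to 1). With only compounds of batches 4 to 6 it moved for hydroxamic acids minus anilides in αTC1 1 h (49 to 3) and βTC3 1 h (93 to 60).

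Replicate numbers do not pair the samples: arrays with the same number had median correlations of 0.013 to 0.028 between their deviations from the group means in the 6 fits, and single pairs went down to -0.73. With the replicate number as a block, in fits of only the arrays compared, the count moved for 5-azadeoxycytidine minus zebuarine in αTC1 24 h (731 to 2129) and hydroxamic acids minus anilides in αTC1 6 h (5286 to 3424), αTC1 24 h (3261 to 1174), βTC3 1 h (93 to 21), βTC3 6 h (5926 to 3875) and βTC3 24 h (3833 to 2321).

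When each replicate or each compound of a class was left out in turn, the count and its lowest and highest values were, for 5-azadeoxycytidine in αTC1 1 h (0, 0 to 1), αTC1 6 h (31, 0 to 91), αTC1 24 h (800, 357 to 492), βTC3 6 h (1, 0) and βTC3 24 h (990, 376 to 938) and 5-azadeoxycytidine minus zebuarine in αTC1 24 h (731, 229 to 806) and βTC3 24 h (27, 1 to 25). It moved likewise for BIX-01294 in αTC1 6 h (517, 125 to 555), αTC1 24 h (189, 63 to 116), βTC3 1 h (3, 2 to 7), βTC3 6 h (1303, 477 to 1336) and βTC3 24 h (142, 51 to 60) and CI-994 minus ITF-2357 in αTC1 24 h (2526, 1629 to 2746). Further moves were for CI-994 minus pyroxamide in αTC1 24 h (1789, 996 to 1789) and ITF-2357 minus pyroxamide in αTC1 24 h (276, 74 to 562) and βTC3 24 h (1927, 1264 to 1912). Others were for chaetocin in αTC1 1 h (13, 4 to 11), βTC3 1 h (2, 2 to 6) and βTC3 6 h (2788, 1855 to 2452) and cyclic tetrapeptides in αTC1 1 h (7, 0 to 3), αTC1 24 h (4250, 2586 to 4456), βTC3 1 h (3, 0 to 15) and βTC3 24 h (3016, 260 to 4266). More followed for hydroxamic acids in αTC1 1 h (70, 27 to 83) and βTC3 1 h (107, 68 to 116) and hydroxamic acids minus anilides in αTC1 1 h (49, 8 to 55) and βTC3 1 h (93, 40 to 107). Counts also moved for anilides in αTC1 1 h (2, 0 to 2) and βTC3 1 h (3, 0 to 3) and scriptaid in αTC1 24 h (50, 2 to 38) and βTC3 24 h (6, 0 to 1). The rest were for zebuarine in βTC3 24 h (397, 129 to 360) and the line difference under 5-azadeoxycytidine (79, 32 to 58), BIX-01294 (26, 8 to 25), cyclic tetrapeptides (2836, 1137 to 2955) and zebuarine (140, 24 to 212). Here fewer arrays also give less power, and an array left alone in its group was taken to vary like those of the other groups.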

Other observations

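The gene groups and the random splits in this part were chosen after the results were seen, and the test of BRD-K62233722 was set down before its value was known.

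Further lists fixed beforehand passed the test in comparisons described above. Under chaetocin at 24 h in βTC3 11 of the 19 neuronal genes fell (11 adjusted over the list alone, and 1 rose, median log2 -0.39, camera adjusted p = 0.00181), with the growth cone protein gene Gap43 at -0.83 ± 0.21 and the synaptic vesicle gene Syp at -0.76 ± 0.16. 7 of the 11 beta cell markers fell (7 adjusted over the list alone, median log2 -0.58, camera adjusted p = 0.00233) there, with Nkx2-2 at -0.97 ± 0.19. 4 of the 7 CDK inhibitors rose (4 adjusted over the list alone, camera adjusted p = 0.0131), led by Cdkn1a (1.19 ± 0.11). The anilides moved neuronal genes upwards in βTC3. There 12 of the 19 neuronal genes rose and 3 fell (12 and 3 adjusted over the list alone, median log2 0.25, camera adjusted p = 0.00558), with the neurofilament gene Nefl at 1.14 ± 0.077 and Snap25, part of the vesicle fusion machinery, at 1.07 ± 0.082. Under 5-azadeoxycytidine 3 of the 10 interferon response genes rose (3 adjusted over the list alone, camera adjusted p = 0.011) in βTC3, with Cxcl10 at 0.96 ± 0.16. BIX-01294 acted on lysosomal genes at 24 h: 2 of the 14 lysosome and autophagy genes rose (2 adjusted over the list alone, camera adjusted p = 4.12e-05) in αTC1, with the sterol carrier gene Npc2 at 0.57 ± 0.10. 3 of the 14 lysosome and autophagy genes rose (4 adjusted over the list alone, camera adjusted p = 2.13e-06) in βTC3. At 6 h under cyclic tetrapeptides 16 of the 18 mitosis genes fell (16 adjusted over the list alone, median log2 -0.94, camera adjusted p = 1e-14) in βTC3. 5 of the 8 alpha cell markers fell (5 adjusted over the list alone, median log2 -0.84, camera adjusted p = 0.00446) in αTC1.

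BRD-K62233722 at 6 h raised 9 of the 17 cholesterol synthesis genes in αTC1 (median log2 0.73, camera adjusted p = 7.46e-79) and 4 in βTC3 (0.26, 4.74e-11). It raised 12 of the 15 ER and amino acid stress genes in βTC3 (0.77, 9.94e-50) against 0 in αTC1 (-0.05, 0.841), by limma. These medians lie near those of BIX-01294, but cholesterol synthesis genes also rose at 6 h under hydroxamic acids, so that list does not single out the pair. A shared response was tested across lines, where no DMSO array is shared. BRD-K62233722 in αTC1 had an r of -0.16 with BIX-01294 in βTC3 (rank 28 of 29), and the reverse pair 0.08 (rank 5.5). Rank 28 lies past the bound set beforehand against a shared response. That bound was wrong, since BIX-01294 with itself (r = 0.06) ranked 14 in that direction and 8 in the other. A shared response stays open.

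For each count of genes the same arrays were also split at random into groups of the same sizes, 100 splits with the real one included. Effects of classes and single compounds, and their line differences, were counted with only the arrays compared, so these real values can differ from those above. Chance here means a random split of single arrays, which parts the arrays of a compound. It therefore does not test how compounds fall into classes, as for hydroxamic acids minus anilides. Each pair of values below is the real count against the highest of the other splits. Chance in this sense can be excluded, with 1 of 100 splits (the real one) giving as many genes, in αTC1 at 1 h for hydroxamic acids minus anilides (24 against 0). The same held in αTC1 at 6 h for hydroxamic acids (5874 against 1523), anilides (2710 against 1201), hydroxamic acids minus anilides (3418 against 899), cyclic tetrapeptides (4455 against 5), BIX-01294 (284 against 75), chaetocin (3414 against 967) and scriptaid (3493 against 1). The same held in αTC1 at 24 h for hydroxamic acids (5916 against 0), anilides (5002 against 1), hydroxamic acids minus anilides (1106 against 57), cyclic tetrapeptides (3578 against 537), chaetocin (5150 against 1) and 5-azadeoxycytidine (1188 against 19). The same held in βTC3 at 6 h for hydroxamic acids (5899 against 0), anilides (3575 against 1316), hydroxamic acids minus anilides (4121 against 4), cyclic tetrapeptides (4032 against 1), chaetocin (2116 against 312) and scriptaid (3502 against 1430). The same held in βTC3 at 24 h for hydroxamic acids (4940 against 25), anilides (4752 against 1042), hydroxamic acids minus anilides (2548 against 288), cyclic tetrapeptides (2600 against 1022), chaetocin (2926 against 899) and 5-azadeoxycytidine (393 against 152). It held also for the lines in DMSO, at 1 h (6948 against 3773), 6 h (6920 against 1) and 24 h (7038 against 5348). So it did for DMSO over time, in αTC1 (859 against 312) and βTC3 (1241 against 3). For the differences between lines, with the limit given above, it held under hydroxamic acids (4241 against 0), anilides (3038 against 2543) and cyclic tetrapeptides (2235 against 293). With that limit it held also under BIX-01294 (14 against 2), chaetocin (2610 against 34) and zebuarine (116 against 15). With 2 of 100 splits as high, the share was under 0.05 in αTC1 at 1 h for hydroxamic acids (65 against 199) and chaetocin (12 against 466). It was so too in βTC3 at 1 h for hydroxamic acids (80 against 86) and hydroxamic acids minus anilides (21 against 105). BIX-01294 in βTC3 had this share at 6 h (988 against 1724) and at 24 h (35 against 49). The line difference under 5-azadeoxycytidine (70 against 132) had it too. In αTC1 the share was 3 of 100 for BIX-01294 at 24 h (156 against 849). For cyclic tetrapeptides at 1 h it was 4 of 100 (4 against 272). Shares of 3 and 4 of 100 lie as near 0.05 as the spread between draws (see zebuarine). The shares were also not adjusted over the results tested, so those of 2 to 4 of 100 exclude chance weakly at best. In βTC3 the counts cannot exclude chance for anilides at 1 h (1 against 250) and zebuarine at 24 h (121 against 340), with 5 of 100 splits each. Nor can they for chaetocin at 1 h (1 against 958, 6 of 100) and 5-azadeoxycytidine at 6 h (1 against 6, 7 of 100). Nor can they for scriptaid at 24 h (1, exceeded by another split, 7 of 100). A second draw for zebuarine gave 3 of 100, at the edge. Yet over the 304 genes plotted above its arrays lay at 0.25 to 0.32 and DMSO arrays up to 0.07, which argues against chance there. Where limma's real count was 0 all 100 splits reach it by construction, which says nothing about chance, in αTC1 at 1 h for anilides (0 against 28), BIX-01294 (0 against 1050) and 5-azadeoxycytidine (0 against 775). That was so too in αTC1 for 5-azadeoxycytidine at 6 h (0 against 679) and zebuarine at 24 h (0 against 252). That was so too in βTC3 at 1 h for cyclic tetrapeptides (0 against 1), BIX-01294 (0 against 84) and 5-azadeoxycytidine (0 against 24). Splits that call several times the real count, up to 1050 genes, point to a structure of the samples, which was not traced to batches. With 3 arrays against 3 there are 10 splits, counted with all arrays of the line and time and too few for a share under 0.05, and 1 of 10 gave as many genes for ITF-2357 minus pyroxamide in αTC1 (276 against 99) and 5-azadeoxycytidine minus zebuarine in αTC1 (731 against 0). In βTC3 the same share was found for ITF-2357 minus pyroxamide (1927 against 57) and CI-994 minus ITF-2357 (2455 against 3). It was also found for CI-994 minus pyroxamide (1511 against 1) and 5-azadeoxycytidine minus zebuarine (27 against 3).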
